A study of Ovis aries with 14 samples.

How the data were processed

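Sperm DNA of 14 samples was analysed, 4 in the group with standard feeding (CON), 5 with over feeding (OVER) and 5 with restricted feeding (RES). They were grouped by the treatment in the labels, and each sample is called a ram below. Per the labels' protocols, sperm were treated with a buffer that lyses somatic cells before DNA extraction, and libraries were made by digestion with MspI, an enzyme that cuts at CCGG whatever the methylation of its CpG, followed by adaptor ligation, bisulfite conversion and size selection on a gel. The series' design text calls the data whole-genome bisulfite sequencing, and the tables listed CpGs throughout the genome, 21663280 of them on the chromosomes in at least 1 ram. Per the submitters' processing notes, Trim Galore 0.4.3, FastQC and Bismark were used, with UMD3.1 given as the genome build. UMD3.1 is a cattle assembly, whereas the tables name 26 numbered chromosomes, X and unplaced scaffolds, the chromosome set of sheep. The assembly behind the coordinates is thus not settled by the sources used here, and positions are given as the tables state them, 1-based.

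Each deposited table gave, per the file headers, 1 cytosine of a CpG per line with its strand, its read coverage as a count and the percent of reads that stayed C or became T. Unconverted C counts as methylated. The deposited counts had a minimum of 3 reads per cytosine in every table, with a median of 4, so that cytosines of lower coverage were not used here. Methylated reads were recovered as coverage times percent, rounded to whole reads.

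Cytosines above the 99.9th percentile of a ram's coverage were left out, each strand taken by itself. Both strands of a CpG were then summed, and reads were summed in adjoining windows of 1000 bp. Where windows were limited to CpGs with 5 or 10 reads or more, that minimum also applied to single cytosines before the strands were summed. A window counted in a ram with 20 or more CpG observations over 3 or more CpGs, and was tested with 3 or more such rams in each group. A ram had a median of 59 CpG observations per tested window, and a median of 12 rams were measured. These observations include several CpGs of 1 read and possible amplification copies, so the dispersion between rams, and not the count, sets the precision. At the median coverage of 4 reads a single CpG of a single ram allows no precise level, and only 3918 CpG sites had 10 or more reads in 3 or more rams of each group.

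Group means of per-ram levels, taken over the 16075 windows measured in all 14 rams, were compared by two-sided exact permutation tests over all assignments of the rams (126 for comparisons with CON and 252 for OVER against RES), whose smallest possible p is 0.00794. Intervals at 95% hold the shifts that this test does not reject. P-values were adjusted by Benjamini-Hochberg within each family of tests. CpG-dense windows are the top 10% by CpG number, 55 or more.

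Differences of single windows and CpG sites were tested by a quasi-binomial model on methylated and unmethylated reads with the group as factor, all 14 rams in 1 fit, Pearson dispersions moderated with limma 3.58.1 (squeezeVar) and kept at 1 or more, and Benjamini-Hochberg adjustment within the comparison at 0.05. The test was run on simulated reads for the 155742 windows with real depths and dispersions, in which 200 windows were changed in OVER at each of 3 sizes. Against CON it found 17.0% of changes of 20 points, 54.5% of 40 points and 90.0% of 60 points, and against RES 36.5%, 69.5% and 93.5%. All 3 sizes were changed in 1 run. Many true changes loosen the Benjamini-Hochberg threshold, so a smaller number of changes would be found less often. The test made 20 and 53 false calls in these comparisons and 1 between the unchanged groups, RES and CON. The 53 stood beside 73, 139 and 187 changes found at the 3 sizes, a share of false calls above 0.05. In OVER against CON the 20 stood beside 34, 109 and 180, a share slightly above 0.05. Of the unchanged windows, 6.94%, 8.82% and 7.47% had an unadjusted p under 0.05 in OVER against CON, OVER against RES and RES against CON, so unadjusted counts run above 5% without any change. The real share for OVER against RES was 5.56%, under the simulated 8.82%, so the simulation did not match the data in full.

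Alternatives, most of them fixed before the data were examined, were minimum CpG coverages of 5 and 10 reads, no upper coverage limit, 50 CpG observations per window, windows of 300 bp, windows measured in every ram, reads thinned to the shallowest ram, edgeR 4.0.16 and limma on M-values (with an offset of 1 read), a replicate block, only the compared groups in the fit, unmoderated dispersions, autosomes only, and each ram left out in turn. Chosen after seeing the data were the removal of each ram's own floor (its median level over windows under 5% in the others), the omission of the 3 rams with a raised floor, and the omission of the 3 rams with few reads in the windows of very high coverage. Tests by chromosome, of the shares of windows and of the windows of very high coverage were also added then.

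By the rule for named regions, up to 4 windows past the adjusted threshold were to be named in each direction. None passed, so the windows named are the 3 with the lowest p of each comparison. Promoter tests, tests of gene lists and classes by exon or intron had been planned. They need an annotation on the coordinates of the tables, which was not used here, and no gene is named. Reads on mitochondrial and unplaced sequence entered no comparison. Computations used Python 3.11.15 with NumPy 2.4.6 and R 4.3.3.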

Results

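CpG methylation was measured by bisulfite sequencing in 14 sperm samples of F1 rams whose dams had received different diets during gestation. The standard-feeding group (CON) held 4 samples, and the over-feeding (OVER) and restricted-feeding (RES) groups held 5 samples each. The series title asks whether maternal nutrition in gestation changes the sperm epigenome of the offspring, and the 3 groups were compared pairwise. Each table listed from 3410396 cytosines in CON replicate 4 to 12497433 in RES replicate 3, with coverages that summed to 20601789 and 85602363. The median coverage was 4 reads per cytosine in every sample, and no listed cytosine had fewer than 3. CON replicates 2, 3 and 4 had the lowest sums, 31524900, 29387871 and 20601789, while those of OVER and RES were 51318172 or more. A read counts in these sums once for each listed cytosine that it covers. Levels were therefore read from windows of 1000 bp, in which CpG reads were summed. The labels number the samples without stating that each came from a separate animal, so the p-values measure the spread between these samples.

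The sperm genome was mostly methylated outside CpG-dense sequence. Of 155742 windows with enough reads in each group, 65.4% had a mean level above 90%, 8.15% lay under 10% and 26.5% lay in between. The windows under 10% held a median of 48 CpGs, against 18 in windows above 90% and 17 in those between. Among these tested windows, adjacent ones under 10% formed 10389 unmethylated runs, of which 244 were 3 kb or longer. In the 16075 windows measured in all 14 rams, the mean level over rams was highest on chromosome 24 (81.5%, 508 windows) and lowest among autosomes on chromosome 6 (58.9%, 467 windows). On the X chromosome it was 59.5% over 37 windows.

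Windows that were unmethylated in the other rams were close to 0 in most libraries and higher in 4. Over windows with a median under 5% in the other 13 rams, the median level was 8.46% in RES replicate 3, 7.81% in OVER replicate 1 and 5.86% in OVER replicate 4. It was 5.21% in CON replicate 2 and at most 1.88% in the remaining 10 rams. In CON replicate 2 the level was uneven, with a 25th percentile of 0 and a 90th percentile of 35.5%. That ram also had the lowest mean over windows methylated above 95% in the others (91.8%, against 94.8% to 97.3%).

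**Figure D1:**
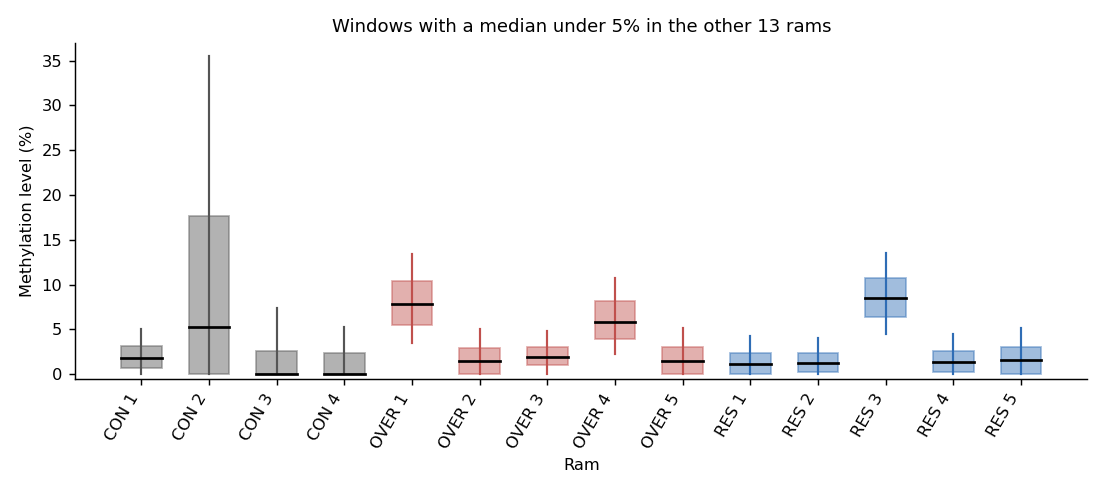
Methylation level (%) in each of the 14 rams over windows with a median under 5% in the other 13 rams. Boxes span the 25th to 75th percentile, thick lines mark the median and thin lines span the 10th to 90th percentile. OVER replicates 1 and 4 and RES replicate 3 are shifted as a whole, to medians of 7.81%, 5.86% and 8.46%, while CON replicate 2 reaches 35.5% at its 90th percentile.

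The comparison of OVER with CON asked whether over-feeding of the dam was followed by another sperm methylation level. The mean level was 72.3% ± 1.28 (SD, n = 5) in OVER and 71.3% ± 0.628 (SD, n = 4) in CON. The difference of 1.05 percentage points had a 95% interval of -0.526 to 2.84 and did not pass a two-sided exact permutation test (p = 0.206, adjusted p = 0.619 over 3 comparisons). It was 0.592 points without OVER replicate 1 and 0.0475 points in windows with 50 or more observations, and it turned with thinned reads (-0.848), pooled reads (-0.133) and CpGs with 10 or more reads (-1.35). OVER had the higher mean on 26 of 27 chromosomes, and chromosome 11 alone had an unadjusted exact p under 0.05 (77.0% against 75.5%, p = 0.0397). After adjustment over 81 chromosome tests that p was 0.804. All chromosomes were measured in the same rams, so the counts of chromosomes in the 3 comparisons are not independent evidence. CpG-dense windows, with 55 or more CpGs, averaged 9.77% ± 2.78 (n = 5) in OVER and 10.2% ± 4.13 (n = 4) in CON (exact permutation p = 0.905). In this class CON replicate 2 stood at 16.3%, and without it the difference was 1.64 points in the other direction. In the remaining, CpG-sparse windows the levels were 79.3% ± 1.12 (n = 5) and 78.1% ± 0.479 (n = 4), a difference of 1.22 points (exact permutation p = 0.0794, adjusted p = 0.81 over 12 class tests). That difference was 0.466 points without the 3 rams of raised floor (OVER replicates 1 and 4 and RES replicate 3) and 0.41 points in windows with 50 or more observations. X chromosome windows averaged 58.6% ± 2.08 (n = 5) in OVER and 61.4% ± 6.02 (n = 4) in CON (exact permutation p = 0.421). CON replicate 2 stood at 69.9% there, and without it the difference was 0.0388 points, with OVER higher.

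Fully methylated windows were more frequent in OVER than in CON before adjustment. Of the 16075 windows measured in all 14 rams, those above 90% made up 56.8% ± 1.52 (SD, n = 5) in OVER and 50.7% ± 5.88 (SD, n = 4) in CON. The difference was 6.09 points, with an exact permutation p of 0.0159 and an adjusted p of 0.0952 over 6 tests that were added after the data had been seen. CON replicates 2 and 3, which were shallow libraries, had the lowest shares, 42.6% and 50.2%, whereas CON replicate 4, the shallowest of all, had 55.2%. Without CON replicate 2 the difference was 3.39 points, and in windows with 50 or more observations 1.99 points (exact permutation p = 0.0238). Leaving out the 3 rams with few reads in the high-coverage windows described below, CON replicates 2 and 3 among them, brought it to 1.75 points (exact permutation p = 0.19). That left 5 OVER and 2 CON rams with 21 assignments, so this p has little power to reject.

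No window and no CpG site passed the adjusted threshold between OVER and CON. The quasi-binomial test with dispersions moderated by limma called 0 of 155742 windows, with 12969 windows (8.33%) at an unadjusted p under 0.05 and a lowest Benjamini-Hochberg adjusted p of 0.546. Both edgeR and limma on M-values called 0 windows, with 7766 and 11019 at an unadjusted p under 0.05. The median absolute difference between group means was 3.46 points. Of the windows at an unadjusted p under 0.05, 76.4% were higher in OVER. Whether other splits of the rams give as uneven a share was not tested. The windows with the lowest p, chosen after their values were seen, were at chromosome 19, 7337001 to 7338000, where OVER had 10.2% ± 9.50 (n = 5) and CON 41.0% ± 17.3 (n = 3), and at chromosome 2. At 202531001 to 202532000 of chromosome 2, OVER had 99.4% ± 0.816 (n = 5) and CON 76.4% ± 16.99 (n = 4), and at 646001 to 647000 OVER had 98.2% ± 1.45 (n = 5) and CON 63.6% ± 20.1 (n = 3). Each of the 3 windows had an adjusted p of 0.546 in the quasi-binomial test, and CON replicate 2 or CON replicate 3 held the value farthest from OVER in each. Among 3918 CpG sites with 10 or more reads, 0 were called by the same test, 267 had an unadjusted p under 0.05 and the lowest adjusted p was 0.119.

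**Figure D2:**
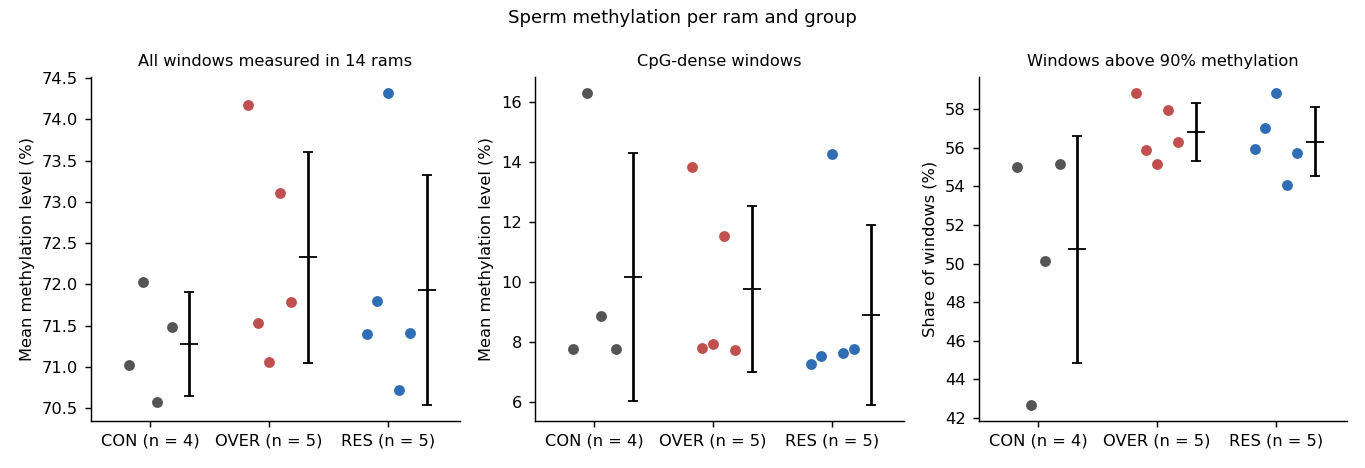
Mean methylation level (%) over all 16075 windows measured in 14 rams and over CpG-dense windows, and share (%) of windows above 90%, for each ram, with the group mean and SD as bars beside the points. The vertical axes do not start at 0. The groups overlap in the first 2 panels, in the third no OVER ram lies below a CON ram (both meet at 55.2%), and CON replicate 2 lies apart in the CpG-dense windows (16.3%) and in the share above 90% (42.6%).

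The comparison of RES with CON asked the same of restricted feeding. The mean level was 71.9% ± 1.39 (SD, n = 5) in RES and 71.3% ± 0.628 (SD, n = 4) in CON, a difference of 0.65 points with a 95% interval of -0.772 to 2.44 (exact permutation p = 0.524, adjusted p = 0.683). Without RES replicate 3 it was 0.0521 points. RES was higher on 25 of 27 chromosomes, and chromosome 16 alone had an unadjusted exact p under 0.05 (75.3% against 74.0%, p = 0.0397, adjusted p = 0.804). The chromosome 16 difference of 1.29 points was 0.758 without RES replicate 3. CpG-dense windows averaged 8.90% ± 3.01 (n = 5) in RES, with RES replicate 3 at 14.3% (exact permutation p = 0.468 against CON). The difference of RES from CON in these windows was -1.27 points. Without RES replicate 3 it was -2.62 points, and without CON replicate 2 it turned to 0.775 points. CpG-sparse windows averaged 79.0% ± 1.23 (n = 5), 0.866 points above CON (exact permutation p = 0.254) or 0.352 points without RES replicate 3, and X chromosome windows 58.8% ± 2.49 (n = 5, exact permutation p = 0.452). Windows above 90% made up 56.3% ± 1.77 (n = 5), 5.59 points more than in CON (exact permutation p = 0.0397, adjusted p = 0.119). Without CON replicate 2 that difference was 2.89 points, with an exact permutation p above 0.05. Leaving out the 3 rams with few reads in the high-coverage windows made it 1.81 points (exact permutation p = 0.133). With 4 RES and 2 CON rams left, the 15 assignments allow no p under 0.05, so that p decides nothing.

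No window passed the adjusted threshold between RES and CON either. The quasi-binomial test called 0 of 155742 windows, with 13633 (8.75%) at an unadjusted p under 0.05 and a lowest adjusted p of 0.473, and edgeR and limma called 0, with 7183 and 11933 windows at an unadjusted p under 0.05. Of the windows at an unadjusted p under 0.05 in the quasi-binomial test, 72.6% were higher in RES. That share rests on the same CON rams as the one for OVER and was not tested either. The lowest p, again chosen after the values were seen, was at chromosome 13, 76306001 to 76307000, a window of 43 CpGs with 29.7% ± 10.7 (n = 4) in RES, 48.5% ± 10.2 (n = 5) in OVER and 88.6% ± 3.57 (n = 3) in CON. At chromosome 7, 62440001 to 62441000, RES had 22.2% ± 3.64 (n = 4), below CON at 74.2% ± 7.83 (n = 4) and OVER at 75.6% ± 22.4 (n = 5). At chromosome 19, 8289001 to 8290000, RES had 99.3% ± 0.730 (n = 5) and CON 83.9% ± 4.83 (n = 3). In all 3 windows every measured RES ram lay on one side of every measured CON ram, and the Benjamini-Hochberg adjusted p was 0.473. Among CpG sites, 0 of 3918 were called, with 276 at an unadjusted p under 0.05. Of the 162 sites with 20 or more reads, 2 passed, at chromosome 16, 31615860 and 31615864. The first had 22.5% ± 18.4 (n = 4) in RES and 62.8% ± 15.4 (n = 3) in CON, and the second 21.2% ± 25.8 (n = 3) and 64.7% ± 15.5 (n = 4), both with an adjusted p of 0.0358 in the quasi-binomial test. They lie so close together that the same reads may cover both, so they are not separate results. Without CON replicate 1, 1 of the sites with 10 or more reads passed, at chromosome 5, 23181718, with 0% in 4 RES rams and 100% in 2 CON rams (adjusted p = 0.0457 in the quasi-binomial test). The SD there was 0 in both groups, and 2 CON rams are under the minimum of 3 set for testing.

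The comparison of OVER with RES set the diets against each other. OVER exceeded RES by 0.402 points in mean level, with a 95% interval of -1.57 to 2.38 (exact permutation p = 0.683, n = 5 each), and without OVER replicate 1 the difference was -0.0578. OVER was higher on 26 of 27 chromosomes, which share the same rams, with 0 of 27 at an unadjusted exact p under 0.05. The share of windows above 90% differed by 0.5 points (exact permutation p = 0.627). CpG-dense windows differed by 0.869 points (exact permutation p = 0.595) and X chromosome windows by -0.172 points (exact permutation p = 0.921).

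The quasi-binomial test called 0 windows between OVER and RES, with 8654 (5.56%) at an unadjusted p under 0.05, and edgeR and limma called 0, with 4503 and 5997 at an unadjusted p under 0.05. The median absolute difference was 2.26 points, and OVER was the higher group in 55.9% of the windows at an unadjusted quasi-binomial p under 0.05. The lowest p belonged to chromosome 12, 47142001 to 47143000, where OVER had 89.5% ± 4.23 (n = 5) and RES 53.1% ± 10.5 (n = 5), near CON at 58.3% ± 11.5 (n = 3), with a quasi-binomial p of 9.41e-07 and an adjusted p of 0.117. At chromosome 3, 1466001 to 1467000, a window of 61 CpGs, OVER had 51.3% ± 13.4 (n = 5) and RES 96.5% ± 0.733 (n = 4), while CON spread around 70.8% ± 26.9 (n = 3). That window had an adjusted p of 0.117 in the quasi-binomial test. It passed with a minimum of 50 CpG observations (adjusted p = 0.0384) and without CON replicate 3, whose spread enters the shared dispersion (adjusted p = 0.00887), the adjusted p ranging from 0.00887 to 1.0 over its alternatives. At chromosome 15, 4346001 to 4347000, the levels were 94.1% ± 6.36 (n = 4) in OVER and 54.6% ± 11.01 (n = 5) in RES (adjusted p = 0.848 in the quasi-binomial test). All 3 windows were chosen after their values were seen. CpG sites gave 0 calls among 3918, with 226 at an unadjusted p under 0.05.

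**Figure D3:**
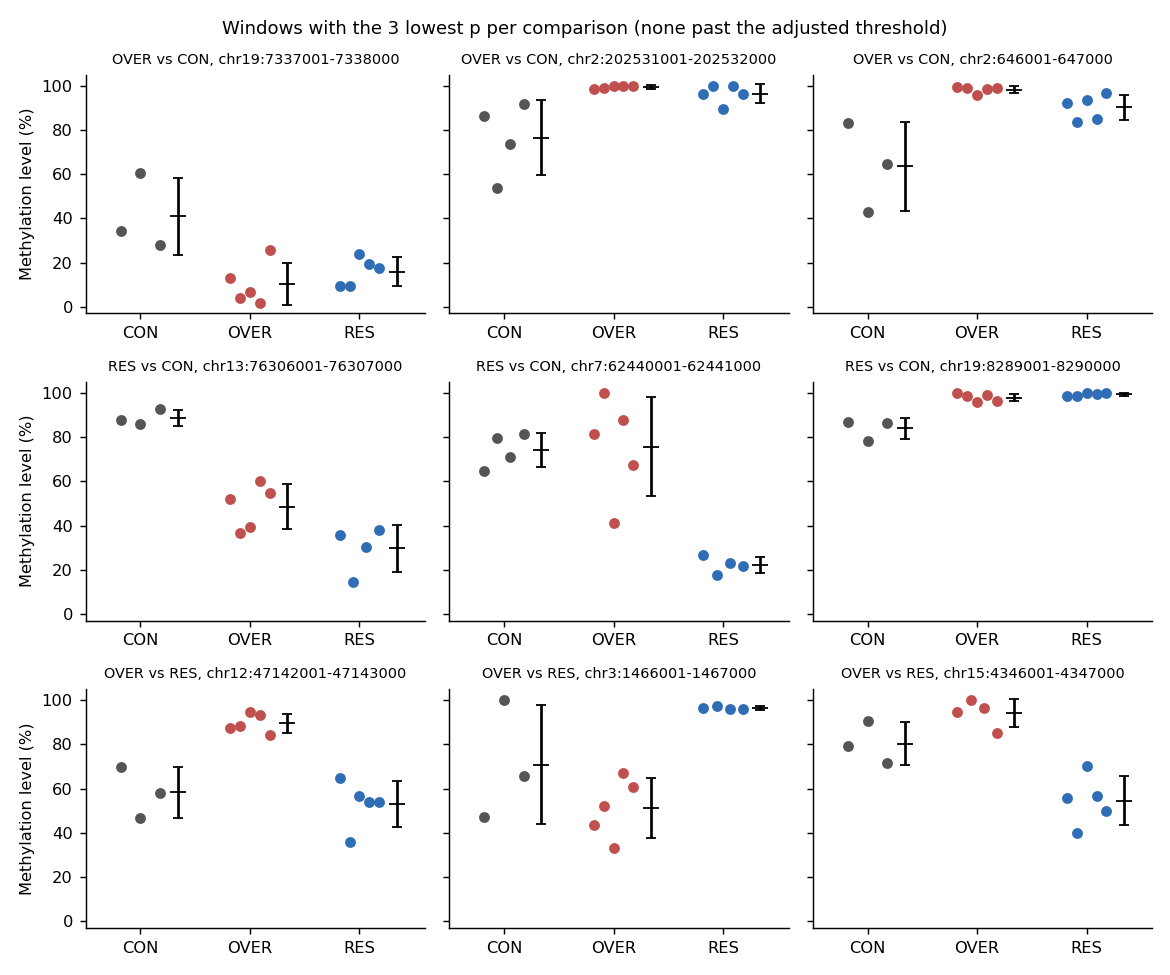
Methylation level (%) of each ram in the 3 windows with the lowest p of each comparison, with group mean and SD as bars beside the points. Levels of the compared groups do not overlap in these windows, which were picked for their low p, and none passed the adjusted threshold (lowest adjusted p = 0.117 for chromosome 12 and chromosome 3).

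The differences of OVER and RES from CON were correlated across windows when all CON rams were shared, and hardly so when they were not. Over the 16075 windows measured in all rams, the differences from CON correlated with r = 0.772 across windows, which are not independent replicates, with a covariance of 31.2. Because the CON rams are shared, regrouping all 14 rams at random gave a mean r of 0.548 and a mean covariance of 17.3 in 100 draws, and 2 of them reached the observed covariance (0 to 10 of 100 when single rams were left out). With the CON rams divided between the comparisons, so that no control was shared, r averaged 0.0273 and ranged from -0.0218 to 0.0641, with a mean covariance of 1.82. Divided in the same way, r averaged 0.069 (0.0233 to 0.101, mean covariance 4.83) with the floor removed. In windows with 50 or more observations it averaged 0.0867 (-0.03 to 0.17, mean covariance 4.3). No window was called in both.

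A set of 13 windows took an outsized share of the coverage. These windows, with a mean coverage of 50 or more in every ram, lay at chromosome 2 (111788001 to 111800000), chromosome 4 (118559001 to 118562000), chromosome 9, chromosome 10 and chromosome 20 (49845001 to 49848000), and up to 23.5% of the CpG coverage on a library's chromosomes fell in them. Their mean level was 33.2% ± 5.44 (SD, n = 5) in OVER, 35.9% ± 6.32 (n = 5) in RES and 44.2% ± 17.1 (n = 4) in CON. The exact permutation p was 0.246 for OVER against CON, 0.365 for RES against CON and 0.484 for OVER against RES (adjusted p = 0.492 or more over 6 tests). The CON mean rested on CON replicates 2 and 3, at 64.4% and 51.8%, and without CON replicate 2 the difference from CON was -4.22 points in place of -10.97 for OVER and -1.52 in place of -8.27 for RES. Leaving out the 3 rams with few reads in these windows turned both differences, to 2.98 and 5.28 points. Only 3.16% of the chromosomal CpG coverage of CON replicate 2, 0.614% of CON replicate 3 and 3.70% of RES replicate 4 fell in these windows, against 12.3% or more in the other rams.

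**Figure D4:**
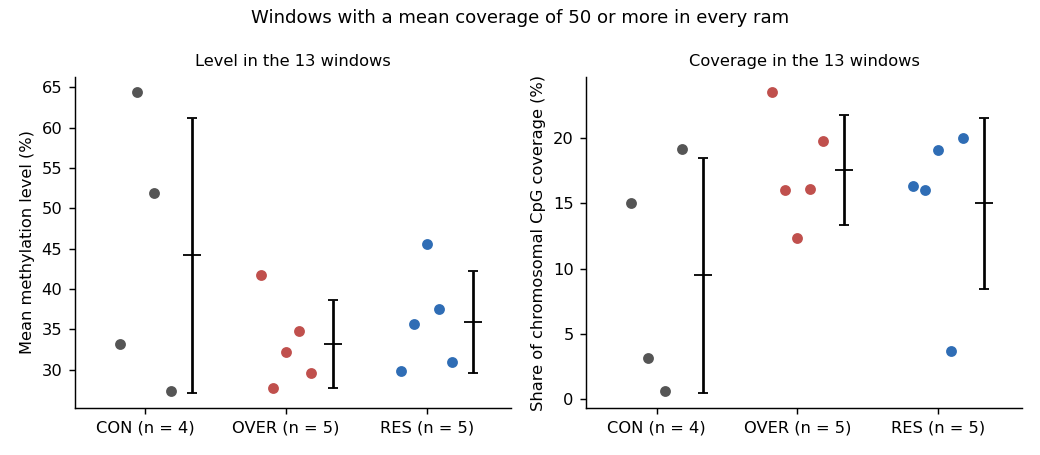
Mean methylation level (%) of the 13 windows of very high coverage, and the share (%) of each library's chromosomal CpG coverage that fell in them, per ram with group mean and SD as bars beside the points. The level axis does not start at 0. CON replicates 2 and 3 have the highest levels (64.4% and 51.8%) and, with RES replicate 4, the smallest shares.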

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

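The tests of explanations given here were chosen after the results had been seen. CON replicate 2 and RES replicates 3 and 4 lay farther from the rest of their group than Dixon's test allows, in 6 of 36 combinations of group and measure examined.

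CON replicate 2 stood apart with a CpG-dense level of 16.3%, against 7.76% to 8.85% in the other CON rams, and with 11.1% of its windows under 10% methylation, against 17.8% to 19.05%. Incomplete bisulfite conversion of this library is argued against by its methylated windows, whose mean of 91.8% lay below the 94.8% or more of every other ram, and by a 25th percentile of 0 in unmethylated windows. Neighbouring windows do not decide whether a shortage of molecules or reads per window was the whole cause. Of the neighbours of windows that gained more than 30 points, 31.7% had gained too, just above a bound of 1.5 times the 19.9% that their CpG number gives. That 19.9% is matched for CpG number but not for depth, which adjacent windows may share. In the other rams 0 to 10.7% of such neighbours had gained, against 0.546% to 2.21% from CpG number, on 40 or fewer pairs each. A comparison of strands left a shortage of molecules and DNA of other cells open too: deviations on forward and reverse reads correlated with r = 0.258 (highest other ram 0.0944). That lay between bounds of 0.1 and 0.3, and a bound of 2 times the highest other ram, chosen with the value known, was dropped. Counting error in the reads of each strand alone leaves the strands uncorrelated, while few molecules read on both strands do not, but this r rests on 1 library. No biological explanation was tested, as the diet is shared with 3 CON rams that did not show the pattern.

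RES replicate 3 had a CpG-dense level of 14.3%, against 7.28% to 7.77% in the other RES rams, a floor of 8.46% over unmethylated windows, against 1.09% to 1.58%, and 11.7% of windows under 10%, against 18.4% to 18.7%, and OVER replicates 1 and 4 had raised floors too (7.81% and 5.86%), without passing Dixon's test. DNA of other cells is argued against, since windows unmethylated in all cells would stay near 0, while the 10th percentile of unmethylated windows was 2.26% or more in these 3 rams and 0 in the others without a raised floor. Incomplete conversion at a single rate would raise both unmethylated and methylated windows. The methylated class was raised too, at 97.1% or more where the other rams reached at most 96.7%, but whether the floors could add that much there was not tested. Intermediate windows left incomplete conversion open: RES replicate 3 (60.5%), OVER replicate 1 (59.8%) and OVER replicate 4 (55.1%) lay above 10 of the other rams (at most 53.7%) and below CON replicate 2 (62.2%). Against the 10 alone, RES replicate 3 and OVER replicate 1 exceed by 2.56 points or more what their floors could add, which argues against a single rate, but with CON replicate 2 counted they do not. The diet stays open and untested: the pattern was seen in 2 of 5 OVER, 1 of 5 RES and 0 of 4 CON rams.

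RES replicate 4 had 3.70% of its chromosomal CpG coverage in the 13 windows of very high coverage, against 15.99% to 19.95% in the other RES rams.

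CpGs outside the chromosomes, which no comparison used, held methylated calls too. Mitochondrial CpGs had a level of 40.1% over a summed coverage of 2695 in 13 rams, ranging from 0.587% on a coverage of 511 in RES replicate 4 to 81.2% on 223 in OVER replicate 5 and 100% on 3 in OVER replicate 1. Unplaced scaffolds had 40.4% over a summed coverage of 33934082, from 33.01% in RES replicate 5 to 63.1% in CON replicate 2.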

How the results depend on the processing

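Omitting the 3 rams with a raised floor or the 3 with few reads in the high-coverage windows, removing the floor, and all alternatives for the window shares, the high-coverage windows and single chromosomes were chosen after seeing the data. Differences are in percentage points, first group minus second, and no cause was tested unless stated. Promoter and gene-list tests were not run, and class tests by annotation neither.

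Global differences changed sign, none past the threshold, under these alternatives: CpGs with 10 or more reads (132 windows, OVER vs CON -1.35, OVER vs RES -1.39), thinned reads (323 windows, OVER vs CON -0.848, RES vs CON -0.253, OVER vs RES -0.595), pooled reads (-0.133, -0.00733 and -0.126), and 50 observations (RES vs CON -0.279, autosomes -0.248). At 50 observations OVER vs CON was 0.0475, and without the raised-floor rams 0.182 (RES vs CON 0.0521). Without single rams OVER vs CON ran from 0.592 to 1.37, RES vs CON from 0.0521 to 0.953 and OVER vs RES from -0.0578 to 1.0, on autosomes from -0.0557 to 1.0, in CpG-sparse windows from -0.048 to 0.864. CpG-sparse OVER vs CON ran from 0.818 to 1.52, passing without OVER replicate 3 only (0.466 without the raised-floor rams, 0.41 at 50 observations), and RES vs CON from 0.352 to 1.17. CpG-dense differences ran from -1.42 to 1.64 (OVER vs CON), -2.62 to 0.775 (RES vs CON) and -0.145 to 2.21 (OVER vs RES), those of the X from -4.29 to 0.0388, -4.11 to 0.211 and -0.978 to 0.49. With the floor removed CpG-dense RES vs CON was -2.36 (exact p = 0.0476, unadjusted) and OVER vs CON -2.27 (exact p = 0.0794), and without the raised-floor rams OVER vs CON was -2.34. The floor, a median, was 0 in CON replicates 3 and 4 and 1.09% or more in every RES ram. Means over the same windows were 2.42% and 1.72% in those 2 CON rams. Removing the floor thus lowers RES more than these CON rams, which limits that p. Without the 3 rams of few high-coverage reads, CpG-dense differences from CON were 2.01 and 1.46, and those of the X 1.43 (OVER vs CON), 0.936 (RES vs CON) and 0.49 (OVER vs RES).

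The share of windows under 10% ran from -1.68 to 1.14 (OVER vs CON), -1.20 to 1.99 (RES vs CON) and -1.84 to 0.514 (OVER vs RES) without single rams, and was -1.96 and -1.84 against CON without the 3 rams of few high-coverage reads. The share above 90% ran from 3.39 to 7.57, 2.89 to 7.07 and -0.0672 to 1.13. It was 5.05 and 4.96 against CON without the raised-floor rams (exact p = 0.2 and 0.143), 1.75, 1.81 and -0.0672 without the few-read rams, and 1.99 against CON in both comparisons at 50 observations (exact p = 0.0238 for OVER and 0.0635 for RES). The level of the high-coverage windows was 2.98 and 5.28 above CON without the few-read rams, and their share of coverage -0.294 in OVER vs RES. That share differed by 8.07 in OVER vs CON (exact p = 0.135), and without single rams by 5.11 to 11.3, passing without CON replicate 4 only (exact p = 0.0357), by 2.58 to 8.75 in RES vs CON and by -0.294 to 3.83 in OVER vs RES. Chromosomes 11 and 16 lost their unadjusted p under 0.05 in 19 of 22 alternatives.

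Window calls stayed at 0 except for OVER vs RES, with 1 at 50 observations and 0 to 1 without single rams. Site calls stayed at 0 except for RES vs CON, with 2 at 20 or more reads, where fewer sites were tested, and 0 to 1 without single rams. Of the 9 named windows 1, at chromosome 3, passed the threshold in 2 alternatives. The correlation of the OVER and RES differences from CON ran from 0.73 to 0.845 without single rams. Replicate numbers did not pair the samples (correlations of deviations from -0.103 to 0.0381). With the replicate block, limma called 0 windows in each comparison (12118, 13203 and 6363 at an unadjusted p under 0.05), and the global differences were 1.19, 0.78 and 0.402. Depth left 3918 sites at 10 or more reads, and 95259 sites at 5 or more reads gave 0 calls too.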

Other observations

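The tests of strands, of spread and of a peak at intermediate levels were chosen after the data had been seen, as was the reading of the splits of the rams. The longest unmethylated run among the tested windows lay at chromosome 17, 24840001 to 24847000, with 387 CpGs over 7 kb. Its level was 2.93% ± 2.83 (SD, n = 5) in RES, 4.06% ± 3.62 (n = 5) in OVER and 6.66% ± 10.6 (n = 4) in CON, where CON replicate 2 alone had 22.6%. Runs of 6 kb followed at chromosome 8, 4219001 to 4225000, and chromosome 10, 5529001 to 5535000, with levels between 1.97% and 3.97% in all 3 groups. None of the 12 longest runs had an exact permutation p under 0.05 in any comparison, the lowest being 0.246 for OVER against RES at chromosome 10.

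The SD between rams was largest where methylation was intermediate. Leaving out CON replicate 2, its median was 12.97 points in windows of 30 to 70% with 50 or more observations, against 3.51 points in windows under 10% and 3.12 points above 90%. Noise, taken from the disagreement of the 2 strands, had an SD of 9.76, 2.52 and 3.04 points in these classes. It was thus also largest at intermediate levels, may make up part of that spread and comes close to the median SD above 90%. The 2 measures differ, however. The noise SD was pooled with each ram's own shift removed, over the windows with enough reads on both strands (1644 of 8332 above 90%). What part of the spread is noise can thus not be read from these values. In 57 of 14968 windows measured in 10 or more rams the SD exceeded 25 points. At chromosome 5, 21995001 to 21996000, levels ran from 0 in RES replicate 1 and 0.84% in OVER replicate 3 to 98.1% in OVER replicate 1. At chromosome 18, 9524001 to 9525000, OVER replicate 5 had 0 and OVER replicate 3 had 93.4%, so that rams of 1 diet spanned nearly the whole range.

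Counting error in the reads of each strand as the whole cause of this spread is argued against, since it leaves the strands uncorrelated. In windows of 30 to 70% a ram's deviations on forward and on reverse reads correlated with r = 0.151, or 0.179 as first computed, before each ram's own shift was removed, and r was positive in all 13 rams (0.0589 to 0.277). Earlier bounds of 0.1 and 0.3 had left this open, but counting alone gives 0, with a standard error of 0.0154. That error takes 4228 pairs of window and ram as independent, though they come from 377 windows and 13 rams. A sampling of few molecules, both strands of which were read, stays open and untested. A hypothesis that the most variable windows carry 2 alleles, methylated and unmethylated, predicts a peak of single rams near 50%. The test decides nothing: over the 57 windows, 106 of 640 levels lay at 40 to 60% and 232 at 20 to 40% or 60 to 80%, a ratio per point of 0.914 with a standard error of 0.107. The windows were chosen for an SD over 25 points, which favours levels far from the middle, and noise of 9.76 points per level may blur a peak.

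Chance could not be excluded for the numbers of windows at an unadjusted p under 0.05. There were 12969 between OVER and CON, which 8 of 100 splits of the rams reached, the real one included, with a highest other of 15199, and 13633 between RES and CON, which 14 of 100 reached with a highest other of 17022. Between OVER and RES there were 8654, which 90 of 100 reached with a highest other of 15999. For windows and sites past the adjusted threshold the splits decide nothing, because any split reaches a real count of 0 (100 of 100). The highest other split called 6 windows for OVER and CON, 2 for RES and CON and 1 for OVER and RES, and 0, 1 and 0 sites. The split with 6 windows, which also had the 15199, set CON replicates 2 and 3 and OVER replicates 1 and 4 against the rest.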
